A study of Mus musculus with 18 samples.

How the data were processed

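Total RNA of FDH cells at passages 10 to 12 was taken from 1000000 cells per condition after growth in 100 ng/ml mouse SCF and doxycycline, or after 2 or 5 days in 100 ng/ml IL-3. Per the submitters' processing notes, reads were aligned to mm10 with STAR and counted per gene, and the values of each file are raw read counts. Versions and the gene annotation are not given in the sources used here. The deposited files, 1 per library, hold read counts of both strands and of each strand for 23329 genes. Counts of the strand that held the reads were used, and the other strand held 1.17 to 2.54% of reads in genes. Reads in no single gene made up 27.9 to 38.1% of a library. In units of 1e6, reads in genes ranged from 13.8 to 27.2.

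Libraries were grouped by receptor and time as labelled, 3 in each of 6 groups. Genes were filtered with filterByExpr at a minimum count of 10, which left 11942, scaled by TMM factors and fitted with 1 mean per group over all 18 libraries by the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3). The common biological coefficient of variation was 0.17. A gene was said to change at a Benjamini-Hochberg adjusted p under 0.05, and the SE is the absolute log2 fold change over the square root of F. The 11 contrasts were day 2 and day 5 against untreated and day 5 against day 2 in each line, P248L against wild-type at each time, and the difference of the lines' responses at day 2 and day 5. For principal components the 1000 genes of highest variance in log2 CPM, at a prior count of 2, were used.

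The 28 gene lists were fixed before the data were examined, as were the tests, the contrasts, the naming rule and the alternatives not marked as added. A list with 5 or more tested members, which held for 24, was tested by camera (limma 3.58.1, preset correlation 0.01, voom values), adjusted over all lists and contrasts, and again with a correlation estimated from the data. Members past the threshold were also counted with adjustment over the list alone. The lists were STAT5-responsive, MAPK feedback, stem and progenitor, primary granule, late neutrophil (with secondary granule), monocyte and macrophage, basophil, mast cell, shared mast cell and basophil, eosinophil, megakaryocyte, erythroid, dendritic cell, lymphoid, hepatocyte with stromal and endothelial, G1/S, G2/M, ribosome biogenesis, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, interferon response, p53 and apoptosis, stress, chemokine, lysosome, mitochondrially encoded and histone genes.

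Genes were named by rule. Per contrast these were the 5 largest rises and 5 largest falls by fitted fold among genes past the threshold, at 10 CPM or more in the higher group, with no overlap of libraries between the groups (a condition not used for the differences of responses) and with a common name. For lists that passed, or with at least 50% of members past the threshold, they were 2 to 4 members of smallest adjusted p, of which the text gives some. The receptor genes, Kit and Hoxb8 were always included. For 1 gene the result is not reported here. Genes of multi-copy families are called uncertain, since reads of near-identical copies can be lost or shared. Folds of genes without reads in a group used a floor of 3 counts over the group, and counting intervals are at a level of 0.95.

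Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 and upper-quartile factors, other filters, a fit of only the libraries compared, the replicate number as a block, stricter thresholds, other list tests and each library left out in turn. Chosen after seeing the data were no scaling beyond library size, counts of both strands, Rn45s left out, P248L untreated library 1 and day 2 library 3 left out together, list tests with libraries left out, and removal of a smooth trend of each library on transcript length and GC, and a replicate block in P248L untreated and day 2 alone. Only in these 2 groups did every same-number pair of a comparison correlate over 0.1 in its deviations from the group means (0.46, 0.17 and 0.35). That pairing comes from the data, and the labels do not say what a number marks. Lengths and GC came from GENCODE M21 transcripts (98.9% of tested genes) and coordinates from RefSeq on GRCm38.p6. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15). Nothing deposited was left out, apart from the other-strand counts, which were used only as stated.

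Every test was tried on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold per contrast. Of the 2-fold genes 79 to 94% were called in the 9 comparisons of groups. In the differences of responses at day 2 and day 5 it was 46 and 43%, so many would be missed. Of the 4-fold genes 97 to 100% were called, and 2.68 to 7.73% of calls were false. The list test called the 1 changed list and 0 of 23 unchanged. Data with more correlated genes, unequal spread or library trends may give other rates, above all in P248L untreated and day 2.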

Results

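RNA was sequenced from FDH cells, which are mouse fetal liver cells of the BALB/c strain, taken from embryos and immortalised. They came from mice without the common beta chain βc and its mouse-specific relative βIL-3, the signalling subunits of the IL-3 receptor, and each line was transduced with βc. One line also carried wild-type IL3Rα, the IL-3-binding subunit, and the other IL3Rα with the amino acid change P248L, named the Site 4 mutant in the series title. Both lines grew in medium with doxycycline and SCF (stem cell factor, the ligand of Kit). They were sampled there, or were washed and kept in medium with IL-3 for 2 or 5 days. The described IL-3 medium lists neither doxycycline nor SCF, so each response below covers the gain of IL-3 together with the loss of both. Each receptor is represented by 1 line, so a difference between receptors is also a difference between lines.

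The 6 groups held 3 libraries each, 18 in all. Reads assigned to genes numbered 17264435, 22627414 and 19621168 in wild-type untreated libraries 1 to 3, 22258820, 17126380 and 18760686 at wild-type day 2 and 19384858, 20671536 and 17257318 at wild-type day 5. The P248L libraries held 26777005, 27181962 and 13844612 untreated, 23124569, 15512850 and 14901822 at day 2 and 23320571, 13898296 and 17563084 at day 5. All library pairs of a group differed by more than sampling noise. Chi-square per degree of freedom was 5.03 to 37.6 in wild-type groups and up to 210 and 193 in P248L untreated and day 2. The labels do not say whether replicates were separate cultures. So p-values measure only sample spread, which may be technical and is pooled over 18 libraries. Levels are counts per 1e6 reads after TMM scaling (CPM), given as the mean of n = 3 libraries with the SD, and log2 fold changes are given with the SE from edgeR. A fold against a group without reads is a lower bound from 3 reads over the group, and with 1 to 3 reads the ratio has a counting interval, and both cover counting error only. In comparisons of groups, genes named for the largest changes had all 3 libraries of one group above all 3 of the other, which chance gives for 10% of genes.

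The first principal component took 69.7% of the variance of the 1000 most variable genes and ordered both lines from untreated to day 5. Wild-type libraries moved from between -55.1 and -51.4 untreated to between 8.88 and 13.5 at day 2, and P248L libraries from between -82.3 and -76.9 to between -61.4 and -57.4. The second component (15%) parted the lines.

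**Figure D1:**
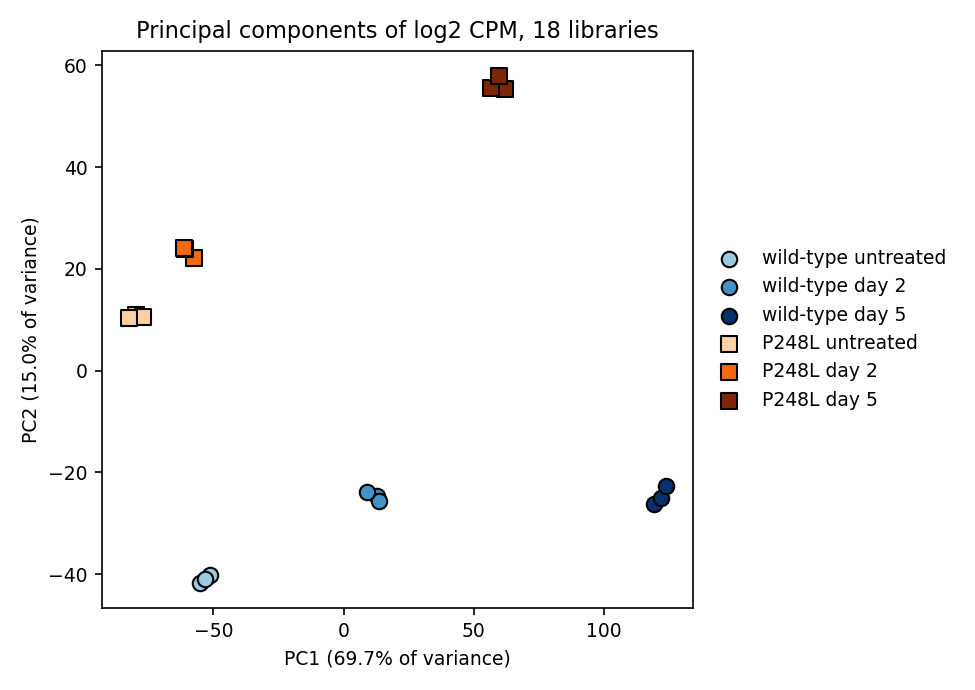
Scores of the 18 libraries on the first and second principal components of log2 CPM (arbitrary units), 1 point per library, coloured by group. P248L libraries lie above wild-type libraries on the second component, and on the first P248L day 2 libraries lie between the untreated libraries of the lines.

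Receptor genes were first read in each sample. Csf2rb, which encodes βc (chromosome 15, 78325800 to 78351001 of GRCm38), stood at 92.1, 80.2 and 77.8 CPM in wild-type untreated libraries 1 to 3, 308, 293 and 213 at day 2 and 456, 429.5 and 427 at day 5. In P248L libraries it stood at 60.4, 67.7 and 64.2, 92.1, 74 and 62.7 and 270.3, 217 and 227 CPM. Its near-identical neighbour Csf2rb2, which encodes βIL-3 (chromosome 15, 78282507 to 78305721), read 102, 104 and 91.4, 352, 374 and 261 and 667, 646 and 627 CPM in the same wild-type groups, and 94.7, 98 and 89, 105, 105 and 96.5 and 339.5, 254 and 307 CPM in P248L groups. Reads can be shared between the pair, and neither the deleted exons nor the species of the transduced βc is given in the labels, so these levels check no genotype. Il3ra (chromosome 14, 14345912 to 14355493) was low throughout, at 7.41, 11.2 and 7.36 CPM in wild-type untreated and 8.93, 6.23 and 3.59 CPM in P248L untreated libraries, 3.05, 2.18 and 2.77 and 2.11, 1.48 and 0.441 at day 2, and 10.5, 9.84 and 7.82 and 2.64, 2.22 and 3.33 at day 5. The labels do not give the species of the transduced IL3Rα either, so whether these reads include it is not known. Csf2ra, the GM-CSF-binding subunit (chromosome 19, 61217191 to 61228461), rose at day 5 from 8.79±1.15 to 173±19.8 CPM (log2 fold change 4.30±0.18) in wild-type and from 6.28±0.731 to 177±19.3 CPM (log2 fold change 4.83±0.19) in P248L cells. Il5ra, the IL-5-binding subunit (chromosome 6, 106710375 to 106749037), fell by day 5 from 2.33±0.66 to 0.175±0.202 CPM (log2 fold change -3.76±0.49) in wild-type and from 2.11±0.257 to 0.118±0.0487 CPM (log2 fold change -4.08±0.52) in P248L cells. Hoxb8, a homeobox gene that can block myeloid differentiation (chromosome 11, 96279401 to 96285325), had 0 reads in all 18 libraries. For these genes the largest edgeR adjusted p of a stated change was 1.8e-06 (Il5ra).

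Cells with the wild-type receptor were first compared between day 2 in IL-3 and growth medium. Kit, Flt3 and Hoxa9 fell, while Ngp, Cish and Cd177 rose. Kit, the SCF receptor (chromosome 5, 75574987 to 75656722), fell from 353±18.2 to 19.9±5.56 CPM (log2 fold change -4.15±0.22). Ngp, a neutrophil granule protein, rose from 5.62±1.13 to 1935±455 CPM (log2 fold change 8.42±0.41), and Cish, a STAT5-induced inhibitor of cytokine signalling, rose from 6.73±0.478 to 155±14.6 CPM (log2 fold change 4.52±0.21). Among the largest rises were Tarm1, an activating receptor of myeloid cells, from 0.0148±0.0256 to 69.3±6.33 CPM, 4782-fold higher, counting interval 858 to 188943, Lipg, which encodes endothelial lipase, from 0.0922±0.0553 to 272±48.3 CPM, log2 fold change 11.49±0.39, and Cd177, a neutrophil surface protein, from 0.197±0.0883 to 163±32.5 CPM, log2 fold change 9.60±0.35. Pknox2, a homeobox transcription factor, went from 0 to 12.9±2.63 CPM, at least 299.6-fold higher, and the anti-apoptotic Bcl2a1b, of a multi-copy family and so uncertain, from 0.0573±0.0685 to 58.9±6.71 CPM, log2 fold change 9.83±0.54. The largest falls were those of Hpgd, a prostaglandin-inactivating enzyme, from 44.2±4.44 to 0.0482±0.0443 CPM, 878-fold lower, counting interval 300.2 to 4261, Flt3, a receptor tyrosine kinase of early progenitors, from 133±8.11 to 0.471±0.279 CPM, log2 fold change -8.12±0.33, and Hoxa9, a homeobox regulator of progenitors, from 169.8±56.6 to 1.6±0.185 CPM, log2 fold change -6.73±0.70. F13a1, a coagulation factor chain found in monocytes, fell from 457±23.6 to 5.85±1.3 CPM, log2 fold change -6.28±0.23, and Hlf, a stem cell transcription factor, from 111±5.54 to 1.68±0.355 CPM, log2 fold change -6.05±0.22. Csf2rb and Csf2rb2 rose by 1.70±0.16 and 1.73±0.14 on the log2 scale, Il3ra fell from 8.65±2.19 to 2.67±0.444 CPM, and Il5ra did not pass (adjusted p = 0.28 in edgeR). The largest edgeR adjusted p among the genes that changed here was 7.1e-04 (Il3ra).

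At day 2 the lists past the threshold were late neutrophil (17 of 18 rose and 1 fell, median 6.02, with the lipocalin gene Lcn2 from 2.0±0.337 to 368±60.9 CPM and Ltf, lactoferrin, from 1.92±0.689 to 113±19.2 CPM), STAT5-responsive (12 of 15 rose, median 2.51, with the kinase gene Pim1 from 32.7±4.85 to 309±21 CPM), stem and progenitor (2 of 17 rose and 13 fell, median -1.48, Prom1 being a riser, from 0.164±0.0804 to 33.6±4.05 CPM) and chemokine and inflammatory genes (10 of 13 rose, median 1.91, with the chemokine gene Ccl6 from 3.22±1.7 to 858±90.5 CPM). In the order given, camera adjusted p = 2.9e-13, 1.4e-06, 3.2e-06 and 1.3e-05, and p = 0.057, 0.079, 0.077 and 0.14 with an estimated correlation. They were also basophil (4 of 5 rose and 1 fell, median 4.66, 4.37 with 1 member at its bound, with Cyp11a1, a steroid-forming enzyme, from 6.14±1.41 to 156±18.1 CPM), shared mast cell and basophil (4 of 5 rose, median 1.23) and MAPK feedback genes (9 of 17 rose and 2 fell, median 0.78, with the immediate-early gene Egr1 from 4.27±1.59 to 127±19.3 CPM). The camera adjusted p = 0.0050, 0.014 and 0.010, and p = 0.079, 0.16 and 0.23 with an estimated correlation. The others were cholesterol synthesis, 12 of 20 rose (median 0.48); glycolysis and hypoxia, 12 of 17 rose and 1 fell (median 0.65); p53 and apoptosis, 7 of 11 rose and 1 fell (median 0.92); amino acid and unfolded protein stress, 11 of 16 rose and 1 fell (median 0.60). For these, camera adjusted p = 0.0014, 0.0018, 0.012 and 0.0011, and p = 0.34, 0.33, 0.079 and 0.14 with an estimated correlation. With adjustment over the list alone, the only other counts were STAT5-responsive 12 up and 1 down, stem and progenitor 2 up and 14 down, genes shared by mast cells and basophils 5 up and 0 down and MAPK feedback 11 up and 2 down. Primary granule genes did not pass as a list although 6 of 9 rose and 2 fell, nor did interferon response genes, of which 3 of 22 rose and 6 fell. By camera, adjusted p = 0.070 and 0.34, and p = 0.46 and 0.68 with an estimated correlation. With the length and GC trend removed the primary granule list passed (camera adjusted p = 0.046). In edgeR 5223 of 11942 tested genes changed, 2630 up and 2593 down. The share up was 50.4%, 41.6% with upper-quartile factors and 36% with no scaling.

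By day 5 the wild-type line had lost ribosome biogenesis transcripts and gained those of the interferon response. Lyz2, lysozyme of macrophages and neutrophils, rose from 66.2±13 to 36326±4156 CPM (log2 fold change 9.10±0.29) and became the most abundant gene of these libraries. Ifit1, an interferon-induced antiviral protein, rose from 0.195±0.106 to 249.9±29.2 CPM (log2 fold change 10.22±0.24), while Mpo, the myeloperoxidase of primary granules, fell from 7073±504 to 6.32±1.76 CPM (log2 fold change -10.12±0.36) and the protease gene Ctsg from 1359.9±55.2 to 1.2±0.685 CPM (log2 fold change -10.11±0.36). The gap junction gene Gja5 rose from 0 to 152±35.7 CPM, at least 3431-fold higher, the membrane glycoprotein gene Pdpn from 0 to 112±31.6 CPM, at least 2528-fold higher and the matricellular gene Nov from 0.129±0.0766 to 1778±245 CPM, log2 fold change 13.66±0.38. Car4, a carbonic anhydrase, rose from 0 to 75.5±50.4 CPM, at least 1667-fold higher, and Tarm1 reached 246±33.9 CPM (17013-fold higher, counting interval 3053 to 672046). Flt3 fell from 133±8.11 to 0.0406±0.0703 CPM, 3236-fold lower, counting interval 896 to 26728, and Nrg2, a neuregulin, from 12.7±2.03 to 0 CPM, at least 205-fold lower. Kit fell from 353±18.2 to 38.7±4.3 CPM, log2 fold change -3.19±0.21, Csf2rb rose by 2.39±0.16 and Csf2rb2 by 2.71±0.14 on the log2 scale, and Il3ra did not pass (adjusted p = 0.75 in edgeR). Among the genes that changed, the largest edgeR adjusted p was 4.2e-07 (Car4).

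Interferon response genes rose together at wild-type day 5: 22 of 22 rose (median 7.86, camera adjusted p = 4.0e-12, p = 0.038 with an estimated correlation), including Zbp1, a nucleic acid sensor, from 0.229±0.0709 to 232±18.6 CPM. Other rising lists were lysosome (16 of 16 rose, median 2.81, with the protease gene Ctsd from 415±35.6 to 31103±3437 CPM), monocyte and macrophage (15 of 19 rose and 3 fell, median 3.92, with Cd68, a macrophage glycoprotein, from 9.96±0.80 to 927±94.7 CPM), late neutrophil (18 of 18 rose, median 6.85, with the metalloproteinase gene Mmp8 from 4.89±0.449 to 1334±135 CPM), chemokine and inflammatory (13 of 13 rose, median 3.92, with Ccl6 from 3.22±1.7 to 19399±1778 CPM) and STAT5-responsive genes (14 of 15 rose, median 3.13). Here camera gave adjusted p = 1.5e-08, 7.3e-05, 1.5e-07, 1.6e-05 and 1.8e-05, and p = 0.079, 0.079, 0.096, 0.14 and 0.084 with an estimated correlation. Ribosome biogenesis genes fell, 17 of 17 fell (median -2.21, camera adjusted p = 1.6e-08, p = 0.014 with an estimated correlation). In the G1/S and DNA replication list 15 of 16 fell (median -2.56), in the G2/M list 14 of 14 fell (median -2.37), in the primary granule list 1 of 9 rose and 7 fell (median -4.44) and in the stem and progenitor list 3 of 17 rose and 14 fell (median -2.25). Their camera adjusted p = 4.5e-08, 1.2e-06, 0.0031 and 7.5e-04, and p = 0.079, 0.074, 0.24 and 0.14 with an estimated correlation. Smaller lists past the threshold were p53 and apoptosis, 8 of 11 rose and 1 fell (median 1.49); dendritic cell and antigen presentation, 6 of 7 rose and 1 fell (median 6.18, 5.01 with 2 members at their bounds); and lymphoid, 4 of 5 rose (median 4.53). List by list, camera adjusted p = 0.010, 0.036 and 0.049, and p = 0.079, 0.18 and 0.18 with an estimated correlation. The lymphoid list was led by Il7r, the IL-7 receptor, from 0.0535±0.0586 to 247±44 CPM. By adjustment over the list alone, each of these counts was the same. Without the length and GC trend the lymphoid list did not pass (camera adjusted p = 0.053). With DESeq2 size factors the dendritic cell and lymphoid lists no longer passed (camera adjusted p = 0.053 and 0.063). Nor did they without P248L untreated library 1 and day 2 library 3 (adjusted p = 0.077 and 0.078), and without 1 library the dendritic cell list was lost for P248L untreated library 1 (0.055) and the lymphoid list for 6 of 18 libraries (up to 0.073). Histone genes went both ways, 4 of 14 rose and 6 fell, as did glycolysis and hypoxia genes, 7 of 17 rose and 3 fell. Camera gave adjusted p = 0.97 and 0.40 in this order, and p = 0.98 and 0.79 with an estimated correlation. Oxidative phosphorylation genes did not pass, 9 of 16 fell (median -0.52, camera adjusted p = 0.0504, p = 0.55 with an estimated correlation), but did with the replicate block (0.049), with the trend removed (0.019), without the 2 libraries named above (0.034) and without each of 16 single libraries (0.0373 to 0.0497). In edgeR 8723 genes changed, 4265 up and 4458 down, 48.9% up, 53.8% with DESeq2 factors and 34.4% with no scaling.

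**Figure D2:**
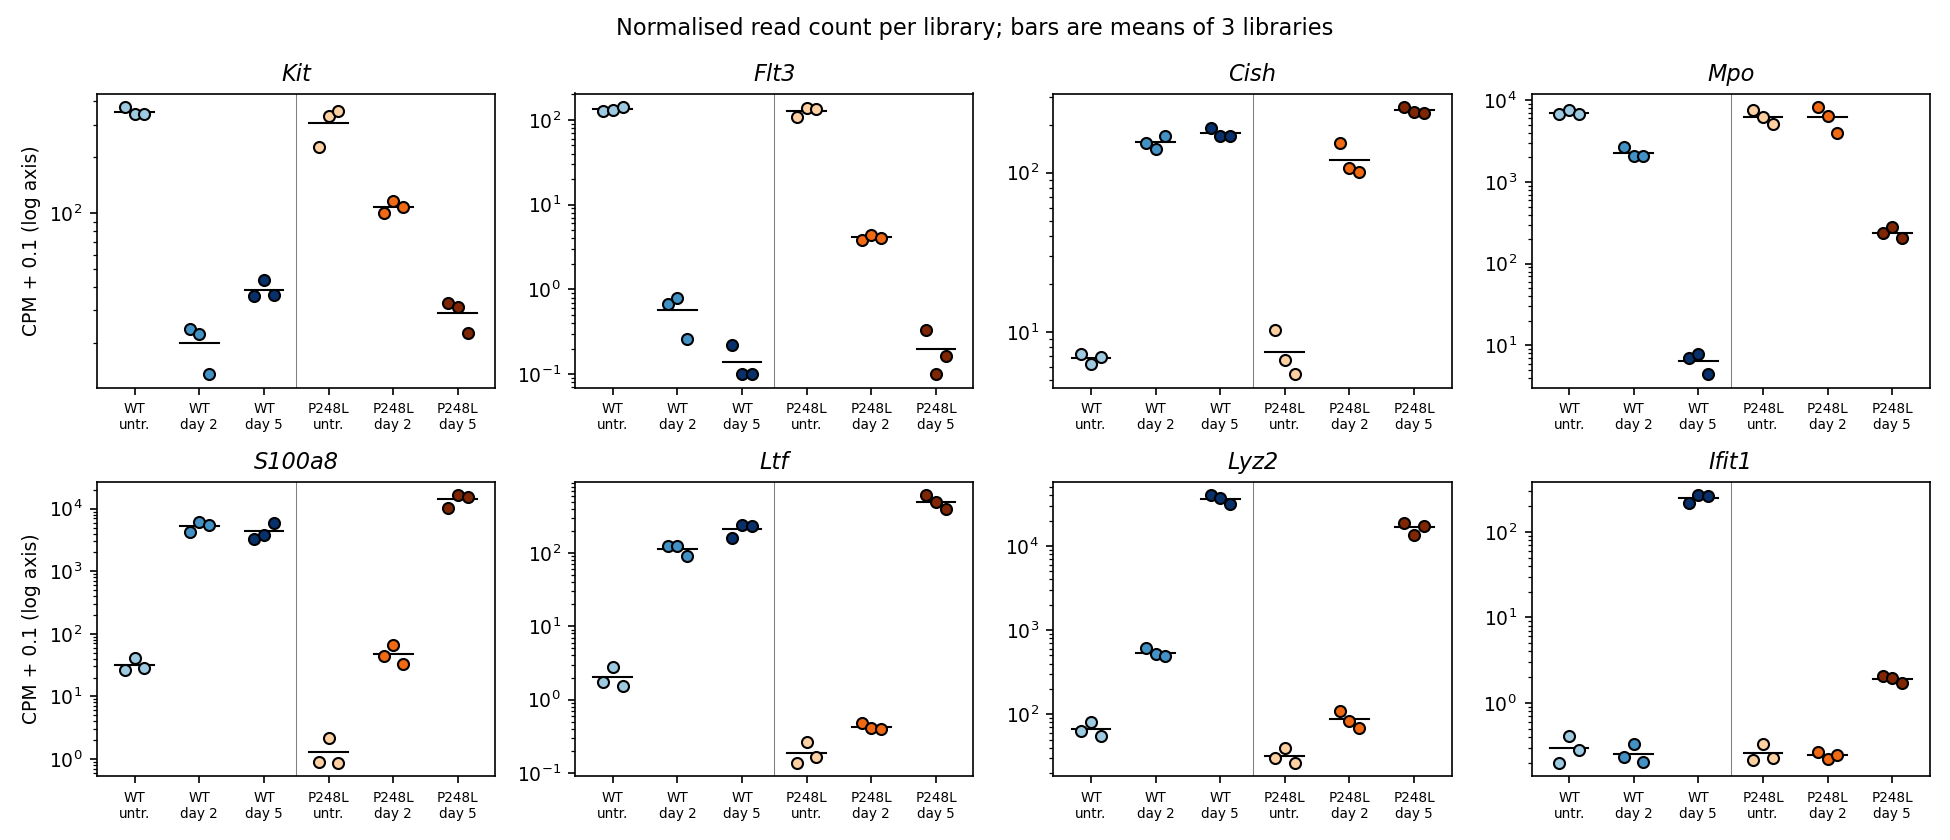
Level of 8 genes in each library (points, CPM plus 0.1 on a log axis) by group, with bars at the group means of 3 libraries. Kit and Flt3 are high in both untreated groups, S100a8 at day 2 is at 5288±945 CPM in wild-type against 47.5±16.4 CPM in P248L cells, and Ifit1 at day 5 is at 249.9±29.2 against 1.82±0.181 CPM.

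Between day 2 and day 5 the wild-type line gained interferon and macrophage transcripts and lost those of ribosome biogenesis. The largest rises were Siglec1, a sialic acid receptor of macrophages, from 0 to 94.1±12.9 CPM, at least 1882-fold higher, Oasl2, an interferon-induced protein, from 0.0145±0.0252 to 208±28.7 CPM, 12471-fold higher, counting interval 2238 to 492622, and Gbp6, an interferon-induced GTPase, from 0 to 27±2.02 CPM, at least 537-fold higher. Pdzk1ip1 went from 0 to 29.6±13.8 CPM, at least 599.7-fold higher and Prickle2, a planar polarity gene, from 0 to 23.6±2.28 CPM, at least 469-fold higher. Mpo fell from 2277±321 to 6.32±1.76 CPM, log2 fold change -8.48±0.33, Elane, the neutrophil elastase gene, from 29.4±5.02 to 0.187±0.111 CPM, log2 fold change -7.26±0.53, and Ms4a3, a granulocyte progenitor gene, from 922±29 to 9.22±1.57 CPM, log2 fold change -6.64±0.20. Ctsg fell by 8.0±0.34 and the inhibitory receptor gene Btla by 5.76±0.33 on the log2 scale. Of the index genes, Kit rose from 19.9±5.56 to 38.7±4.3 CPM and Il3ra from 2.67±0.444 to 9.4±1.41 CPM. In edgeR the largest adjusted p of these was 4.1e-04 (Kit). Interferon response genes (22 of 22 rose, median 8.33, 8.13 with 1 member at its bound), monocyte and macrophage genes (16 of 19 rose and 1 fell, median 4.09) and lysosome genes (16 of 16 rose, median 2.61) moved up. In the order given, camera adjusted p = 6.8e-13, 2.2e-07 and 7.3e-09, and p = 0.036, 0.039 and 0.079 with an estimated correlation. The macrophage list was led by Ctss, a lysosomal protease, from 20.8±3.23 to 4762±488 CPM. Downward lists were ribosome biogenesis (17 of 17 fell, median -2.68), G1/S (15 of 16 fell, median -2.58), G2/M (14 of 14 fell, median -2.53) and primary granule (9 of 9 fell, median -4.69). The camera adjusted p = 6.6e-10, 7.3e-09, 1.3e-07 and 9.5e-06, and p = 0.0094, 0.079, 0.057 and 0.10 with an estimated correlation. Chemokine genes (11 of 13 rose and 1 fell, median 2.13) and dendritic cell genes (6 of 7 rose, median 3.25) went up, cholesterol synthesis (12 of 20 fell, median -0.65) and oxidative phosphorylation genes (1 of 16 rose and 11 fell, median -0.71) down. For these, camera adjusted p = 0.0046, 0.018, 0.0079 and 0.026, and p = 0.33, 0.14, 0.43 and 0.51 with an estimated correlation. Adjusted over the list alone, each of these counts was the same. With the length and GC trend removed the oxidative phosphorylation list did not pass (camera adjusted p = 0.054). Late neutrophil genes were divided, 7 of 18 rose and 7 fell (camera adjusted p = 0.78, p = 0.90 with an estimated correlation). STAT5-responsive genes did not pass, 9 of 15 rose and 2 fell (camera adjusted p = 0.051, p = 0.39 with an estimated correlation), but did with the replicate block (0.049) and without each of 4 single libraries (0.0389 to 0.0479). The edgeR calls numbered 8429, 4296 up and 4133 down, 51% up and 40.5% with no scaling.

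The line with the P248L receptor was compared in the same way. At day 2 Cish, Pim1 and S100a8 rose and Kit and Hoxa9 fell. Cish rose from 7.32±2.51 to 119.9±28.8 CPM (log2 fold change 4.02±0.21) and Pim1 from 49.6±5.47 to 421±57.6 CPM (log2 fold change 3.08±0.15). Kit fell from 305±67.5 to 108±7.86 CPM (log2 fold change -1.49±0.20), and S100a8, a subunit of the neutrophil protein calprotectin, rose from 1.2±0.724 to 47.5±16.4 CPM (log2 fold change 5.23±0.40). Other large rises were those of Vat1l from 0 to 10.7±1.71 CPM, at least 256-fold higher, C3ar1, the complement C3a receptor, from 0.319±0.227 to 16.4±3.68 CPM, log2 fold change 5.84±0.31, and Pilra, an inhibitory receptor of myeloid cells, from 0.33±0.134 to 19.6±1.56 CPM, log2 fold change 5.77±0.21. Serpinb9g, a protease inhibitor of a multi-copy family and so uncertain, rose from 0.0359±0.0376 to 12.8±9.75 CPM, 271-fold higher, counting interval 92.2 to 1316. Falls were led by Susd5 from 12.4±2.58 to 0.128±0.0897 CPM, log2 fold change -6.71±0.45, H2-Ob, an antigen presentation gene, from 30.3±6.96 to 0.539±0.178 CPM, log2 fold change -5.73±0.26, and Hoxa9 from 83.8±68.1 to 1.64±0.446 CPM, log2 fold change -5.63±0.68. The IL-12 subunit gene Il12a fell by 5.6±0.33 and the fatty acid transporter gene Slc27a1 by 5.23±0.36 on the log2 scale. Il3ra fell from 6.25±2.67 to 1.34±0.842 CPM and Csf2ra rose from 6.28±0.731 to 14.6±3.43 CPM, while Csf2rb and Csf2rb2 did not pass (edgeR adjusted p = 0.20 and 0.50). Among the genes that changed, the largest edgeR adjusted p was 2.5e-04 (Il3ra).

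In P248L day 2 cells STAT5-responsive (11 of 15 rose and 1 fell, median 1.07), ribosome biogenesis (13 of 17 rose, median 0.59) and late neutrophil genes (11 of 18 rose and 1 fell, median 2.45) rose as lists, as did primary granule (4 of 9 rose and 1 fell, median 0.77) and stress genes (8 of 16 rose and 2 fell, median 0.35), and stem and progenitor genes fell (1 of 17 rose and 11 fell, median -1.01, with Flt3 from 127±16.1 to 4.0±0.295 CPM). By camera, adjusted p = 1.2e-04, 2.0e-05, 4.7e-05, 0.033, 0.016 and 2.5e-05, and p = 0.11, 0.056, 0.18, 0.39, 0.24 and 0.079 with an estimated correlation. Interferon response genes went down as a list, 1 of 22 rose and 10 fell (median -0.59), as did histone genes, 7 of 14 fell (median -1.07). Here camera gave adjusted p = 0.024 and 0.0076, and p = 0.35 and 0.22 with an estimated correlation. With adjustment over the list alone, the only other counts were stem and progenitor 2 up and 12 down, late neutrophil 12 up and 1 down, primary granule 5 up and 1 down, interferon response 1 up and 11 down and histone 0 up and 8 down. With the replicate number as a block in these 6 libraries the interferon list did not pass (camera adjusted p = 0.059). The primary granule list was lost without P248L untreated library 3 or day 2 library 1 (0.095 and 0.099), and the stress list without untreated library 3 (0.064). Without the length and GC trend the histone list no longer passed (camera adjusted p = 0.086). Without P248L untreated library 1 and day 2 library 3 the medians were 1.56 for STAT5-responsive and 1.26 for primary granule genes. MAPK feedback genes did not pass as a list, 3 of 17 rose and 4 fell, nor did chemokine genes, 5 of 13 rose and 3 fell. Their camera adjusted p = 0.85 and 0.74, and p = 0.91 and 0.89 with an estimated correlation. In edgeR 4762 genes changed, 2204 up and 2558 down, 46.3% up, 53.1% with DESeq2 factors, 36.2% with upper-quartile factors and 34.3% with no scaling. A fit of these 6 libraries alone called 1630 genes.

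By day 5 P248L cells had lost ribosome biogenesis transcripts. Ltf rose from 0.0885±0.0666 to 504±107 CPM (log2 fold change 12.27±0.39) and Lyz2 from 31.8±6.63 to 16616±2661 CPM (log2 fold change 9.02±0.29). Fpr1, the formyl peptide receptor of phagocytes, rose from 0 to 111±15.4 CPM, at least 2758-fold higher, Prom1 from 0 to 105±9.23 CPM, at least 2503-fold higher, and Capn2, a calpain protease, from 0 to 104±6.25 CPM, at least 2537-fold higher. The kallikrein gene Klk1b11, of a multi-copy family and so uncertain, went from 0 to 131±40.1 CPM, at least 3334-fold higher, and Emp1 from 0 to 109±10.3 CPM, at least 2635-fold higher. Flt3 fell from 127±16.1 to 0.0981±0.12 CPM, log2 fold change -10.0±0.39, and Amot, which encodes angiomotin, from 36±16.6 to 0.0928±0.0406 CPM, log2 fold change -8.42±0.52. Tmem176b fell by 6.94±0.39 and its neighbour Tmem176a fell by 6.92±0.59 on the log2 scale. Kit fell from 305±67.5 to 28.9±5.61 CPM, log2 fold change -3.40±0.22, Il3ra from 6.25±2.67 to 2.73±0.556 CPM, log2 fold change -1.21±0.35, and Csf2rb and Csf2rb2 rose by 1.89±0.16 and 1.68±0.14 on the log2 scale. Of this set the largest edgeR adjusted p was 0.0056 (Il3ra).

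The late neutrophil list led the P248L day 5 response: 18 of 18 rose (median 10.23, camera adjusted p = 6.6e-10, p = 0.079 with an estimated correlation). Monocyte and macrophage genes (14 of 19 rose and 2 fell, median 3.18, camera adjusted p = 6.0e-06, p = 0.070 with an estimated correlation) included Csf1r, the macrophage growth factor receptor, from 5.24±0.336 to 223±30.01 CPM. Chemokine (13 of 13 rose, median 3.57), lysosome (15 of 16 rose and 1 fell, median 1.80) and STAT5-responsive genes (12 of 15 rose and 1 fell, median 3.08) rose. List by list, camera adjusted p = 1.8e-05, 1.6e-05 and 4.4e-04, and p = 0.14, 0.14 and 0.14 with an estimated correlation. Rising too were glycolysis and hypoxia genes, 16 of 17 rose (median 1.21), cholesterol synthesis genes, 13 of 20 rose (median 0.64), interferon response genes, 16 of 22 rose and 1 fell (median 2.05), p53 and apoptosis genes, 7 of 11 rose and 1 fell (median 1.16), and MAPK feedback genes, 10 of 17 rose and 3 fell (median 1.56). Camera gave adjusted p = 8.6e-05, 0.013, 4.5e-04, 0.020 and 0.042 in this order, and p = 0.23, 0.45, 0.16, 0.084 and 0.33 with an estimated correlation. Falling lists were ribosome biogenesis (17 of 17 fell, median -1.97), G1/S (16 of 16 fell, median -1.88), G2/M (13 of 14 fell, median -1.10), oxidative phosphorylation (16 of 16 fell, median -0.78) and stem and progenitor (2 of 17 rose and 14 fell, median -2.73). In the order given, camera adjusted p = 1.6e-08, 1.8e-07, 3.8e-04, 3.8e-04 and 1.2e-04, and p = 0.014, 0.084, 0.12, 0.31 and 0.087 with an estimated correlation. By adjustment over the list alone, each of these counts was the same. With DESeq2 size factors the MAPK list no longer passed (camera adjusted p = 0.052), nor without P248L untreated library 1 (0.082), day 2 library 3 (0.052) or both (0.11). Primary granule genes were divided, 4 of 9 rose and 5 fell (camera adjusted p = 0.42, p = 0.75 with an estimated correlation). In edgeR 8474 genes changed, 4152 up and 4322 down, 49% up and 40.2% with no scaling.

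From day 2 to day 5 in P248L cells ribosome biogenesis transcripts fell. Fpr1 rose from 0 to 111±15.4 CPM, at least 2048-fold higher, Eno2, a neuronal enolase, from 0 to 21.7±6.01 CPM, at least 407-fold higher, and Dennd2a from 0 to 44.7±8.82 CPM, at least 832-fold higher. From multi-copy families, and so uncertain, Retnlg, a resistin-like gene, went from 0 to 94.4±9.19 CPM, at least 1690.4-fold higher and Stfa3, a stefin, from 0.361±0.318 to 1503±299 CPM, log2 fold change 11.80±0.53. Coagulation factor gene F12 fell from 14.1±9.0 to 0.358±0.276 CPM, log2 fold change -5.21±0.71, Ccnb1ip1 from 71.8±1.89 to 2.17±0.803 CPM, log2 fold change -5.06±0.26 and Rangrf from 10.6±3.75 to 0.329±0.206 CPM, log2 fold change -5.05±0.38. Ctsg fell from 570.3±145 to 18.6±0.686 CPM, Mpo from 6201±2186 to 240.0±37.5 CPM and the collagen gene Col4a2 by 4.73±0.33 on the log2 scale. Kit fell from 108±7.86 to 28.9±5.61 CPM and Csf2rb rose from 76.3±14.8 to 238±28.4 CPM. The largest edgeR adjusted p was 3.8e-06 (F12). Rising lists were late neutrophil (18 of 18 rose, median 7.48), monocyte and macrophage (15 of 19 rose, median 3.83), lysosome (15 of 16 rose, median 1.68), interferon response (20 of 22 rose and 1 fell, median 3.73), chemokine (11 of 13 rose, median 4.51), glycolysis (15 of 17 rose, median 0.99), cholesterol synthesis (13 of 20 rose, median 0.68) and MAPK feedback genes (10 of 17 rose and 2 fell, median 1.11). The camera adjusted p = 3.8e-09, 1.7e-06, 4.3e-06, 3.1e-05, 5.7e-05, 0.0015, 0.020 and 0.041, and p = 0.079, 0.056, 0.13, 0.11, 0.18, 0.33, 0.49 and 0.33 with an estimated correlation. Lists that fell were ribosome biogenesis (17 of 17 fell, median -2.67), G1/S (15 of 16 fell, median -1.95), G2/M (13 of 14 fell, median -1.41), oxidative phosphorylation (11 of 16 fell, median -0.60), stem and progenitor (2 of 17 rose and 10 fell, median -0.60) and primary granule (1 of 9 rose and 6 fell, median -1.49). For these, camera adjusted p = 2.0e-10, 2.6e-08, 1.7e-05, 0.0030, 0.013 and 0.019, and p = 0.0094, 0.079, 0.079, 0.39, 0.24 and 0.35 with an estimated correlation. Adjusted over the list alone, the only other counts were G2/M 0 up and 14 down and stem and progenitor 2 up and 11 down. The MAPK list was lost without P248L untreated library 1, day 2 library 3 or both (camera adjusted p = 0.062, 0.061 and 0.094), and without both the stem and progenitor median was -0.99. STAT5-responsive genes did not pass, 11 of 15 rose and 2 fell (camera adjusted p = 0.051, p = 0.38 with an estimated correlation), but did with the replicate block (0.046) and without each of 10 single libraries (0.0427 to 0.0497). In edgeR 8372 genes changed, 4428 up and 3944 down.

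The lines were then compared with each other in the same medium, wild-type level first. Before IL-3, Gpc3, a cell surface proteoglycan, was higher at 0.354±0.162 against 30.4±4.03 CPM (log2 fold change 6.41±0.34), Kcnn4, a calcium-activated potassium channel, at 2.77±0.102 against 81±25.4 CPM (log2 fold change 4.87±0.30), and Chd3, a chromatin remodeller, at 1.5±0.439 against 71.5±19.4 CPM (log2 fold change 5.57±0.30). Slc16a7, a monocarboxylate transporter, was higher by 6.21±0.37 and the growth factor receptor gene Pdgfrb by 5.43±0.38 on the log2 scale. Hpgd was lower at 44.2±4.44 against 0 CPM (at least 1074-fold lower), Maoa, monoamine oxidase A, at 45.4±0.271 against 0 CPM (at least 1100.2-fold lower), and Lonrf3 at 24.3±1.85 against 0 CPM (at least 588-fold lower). Lower too were Svil, an actin-binding protein gene, at 64.2±6.08 against 0.0109±0.0189 CPM (4647-fold lower, counting interval 834 to 183605), and Arhgap12 at 19±1.34 against 0 CPM (at least 458-fold lower). Kit (353±18.2 against 305±67.5 CPM), Csf2rb, Csf2rb2, Csf2ra, Il3ra and Il5ra did not pass, the smallest edgeR adjusted p being 0.052 (Csf2ra). The largest edgeR adjusted p among the genes that differed was 7.6e-09 (Pdgfrb). Late neutrophil genes were 1 of 18 higher and 9 lower (median -2.35), such as S100a8 at 31.7±8.2 against 1.2±0.724 CPM, and macrophage genes 2 of 19 higher and 10 lower (median -0.97), such as Csf1r at 32.1±3.54 against 5.24±0.336 CPM. By camera, adjusted p = 3.1e-04 and 0.0040, and p = 0.23 and 0.14 with an estimated correlation. Histone genes were 8 of 14 higher (median 1.32), oxidative phosphorylation genes 6 of 16 higher (median 0.45), ribosome biogenesis genes 4 of 17 higher (median 0.23) and G1/S genes 2 of 16 higher (median 0.20). Here camera gave adjusted p = 4.7e-05, 6.5e-04, 0.013 and 0.012, and p = 0.084, 0.33, 0.14 and 0.37 with an estimated correlation. With adjustment over the list alone, the only other counts were late neutrophil 1 up and 10 down, monocyte and macrophage 2 up and 11 down, oxidative phosphorylation 10 up and 0 down and G1/S 1 up and 0 down. Folds of this contrast ran with transcript length (Spearman correlation -0.53 across genes, which are not independent replicates), and histone and oxidative phosphorylation transcripts have median lengths of 782 and 1679 bases against 3034 for all genes tested. With the length and GC trend removed the histone, oxidative phosphorylation, ribosome biogenesis and G1/S lists still passed (camera adjusted p = 0.011, 0.013, 0.010 and 0.0041), and the primary granule list also passed, as lower (0.0015 against 0.17). Without P248L untreated library 1, where Mki67, a proliferation gene, was at 276 CPM against 568 and 916 in its group, 1 oxidative phosphorylation gene was higher (list median 0.26). In edgeR 2571 genes differed, 1225 higher and 1346 lower in P248L cells, 47.6% higher and 35.9% with no scaling. The count was 1557 without wild-type untreated library 1, 1517 without library 3, 1678 without P248L untreated library 1 and 4541 without library 3.

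At day 2 P248L cells held more ribosome biogenesis transcripts than wild-type cells. S100a9, the other calprotectin subunit, was lower at 8577±945 against 50.3±16.4 CPM (log2 fold change -7.41±0.40), Ngp at 1935±455 against 1.18±0.908 CPM (log2 fold change -10.55±0.46) and Ccl6 at 858±90.5 against 21.4±6.08 CPM (log2 fold change -5.32±0.38), while Kit was higher at 19.9±5.56 against 108±7.86 CPM (log2 fold change 2.44±0.21). Other higher genes were Elavl2, an RNA-binding protein of neurons, at 0.179±0.0787 against 24±5.88 CPM (log2 fold change 6.97±0.38), S1pr3, a sphingosine phosphate receptor, at 0.581±0.105 against 11±1.76 CPM (log2 fold change 4.25±0.22), and Eng, endoglin, at 0.986±0.133 against 14.3±6.34 CPM (log2 fold change 3.86±0.31). Chd3 and Kcnn4 stayed higher in P248L cells by 4.94±0.31 and 4.93±0.32 on the log2 scale. Among the lowest were the scaffold gene Gphn at 36.3±2.36 against 0 CPM (at least 649.6-fold lower), the mitochondrial protein gene Chchd10 at 20.5±1.84 against 0 CPM (at least 371-fold lower), and Ckap4, a membrane protein gene, at 72±10.04 against 0.0138±0.0239 CPM (3873-fold lower, counting interval 695 to 153003). The ubiquitin ligase gene Rnf217 was at least 325-fold lower, and Lonrf3 3059-fold lower, counting interval 549 to 120847. Csf2rb and Csf2ra were lower in P248L cells by log2 fold changes of -1.83±0.16 and -1.79±0.17. Of these genes the largest edgeR adjusted p was 1.6e-07 (Csf2ra). In P248L day 2 library 3 the ribosomal RNA gene Rn45s took 3.44% of reads, 37741 CPM against 1233 and 1499 in libraries 1 and 2. Late neutrophil genes were 16 of 18 lower (median -4.99), chemokine genes 11 of 13 lower (median -2.66) and MAPK feedback genes 1 of 17 higher and 11 lower (median -1.72), such as Egr1 at 127±19.3 against 5.96±2.13 CPM. Their camera adjusted p = 7.5e-14, 1.1e-06 and 3.8e-04, and p = 0.056, 0.11 and 0.11 with an estimated correlation. Basophil genes were 4 of 5 lower (median -2.26), genes shared with mast cells 4 of 5 lower (median -1.28), p53 and apoptosis genes 1 of 11 higher and 7 lower (median -0.73), cholesterol synthesis genes 9 of 20 lower (median -0.42) and STAT5-responsive genes 1 of 15 higher and 8 lower (median -0.96). List by list, camera adjusted p = 0.0018, 0.0012, 0.011, 0.011 and 0.027, and p = 0.075, 0.084, 0.079, 0.44 and 0.33 with an estimated correlation. Higher in P248L cells were ribosome biogenesis genes, 14 of 17 higher (median 0.54), G1/S genes, 7 of 16 higher (median 0.30), and stem and progenitor genes, 8 of 17 higher and 3 lower (median 0.36). Camera gave adjusted p = 1.4e-06, 0.0022 and 0.013 in this order, and p = 0.036, 0.28 and 0.24 with an estimated correlation. By adjustment over the list alone, the only other counts were MAPK feedback 1 up and 12 down, ribosome biogenesis 16 up and 0 down, G1/S 8 up and 0 down and stem and progenitor 9 up and 3 down. Without wild-type day 2 library 2 the cholesterol list did not pass (camera adjusted p = 0.061). Without the length and GC trend the stem and progenitor list no longer passed (camera adjusted p = 0.078). In edgeR 4253 genes differed, 1833 higher and 2420 lower.

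At day 5 interferon response transcripts were lower in P248L than in wild-type cells. Ifit1 was at 249.9±29.2 against 1.82±0.181 CPM (log2 fold change -7.09±0.20), and Isg15, a ubiquitin-like interferon-induced protein, at 117±16.2 against 2.57±0.165 CPM (log2 fold change -5.50±0.19). Mpo was higher at 6.32±1.76 against 240.0±37.5 CPM (log2 fold change 5.24±0.29), Elane at 0.187±0.111 against 11.8±1.46 CPM (log2 fold change 5.95±0.54), and Egln3, an oxygen-sensing hydroxylase, at 36.3±30.03 against 638±107 CPM (log2 fold change 4.14±0.38). The Serpinb9f, Serpinb9e and Serpinb9g genes, of 1 multi-copy family and so uncertain, were higher at 0.019±0.0328 against 64.6±6.99 CPM (3155-fold higher, counting interval 566 to 124668), 0.0416±0.0365 against 89.3±13.7 CPM (2188-fold higher, counting interval 605 to 18071) and 1.22±0.311 against 499±121 CPM (log2 fold change 8.66±0.61), and Elavl2 at 0.135±0.143 against 17.3±3.79 CPM (log2 fold change 6.85±0.40). The largest gaps downward were Lonrf3 at 214±20.4 against 0 CPM (at least 3591-fold lower), Car4 at 75.5±50.4 against 0 CPM (at least 1231-fold lower), and Rragd, a GTPase of amino acid sensing, at 54.7±13.4 against 0 CPM (at least 928-fold lower). Fpgt was at least 785-fold lower and Svil 6744-fold lower, counting interval 1210.0 to 266427. Cpa3, a carboxypeptidase of mast cells and basophils, was at 2552±490.2 against 37.8±10.4 CPM (log2 fold change -6.08±0.24). Csf2rb, Csf2rb2 and Il3ra were lower by log2 fold changes of -0.88±0.15, -1.11±0.13 and -1.78±0.36, and Kit did not pass (edgeR adjusted p = 0.099). The largest edgeR adjusted p among the genes that differed was 5.0e-04 (Il3ra). Interferon response genes were 22 of 22 lower (median -5.31), lysosome genes 15 of 16 lower (median -1.13), genes shared by mast cells and basophils 4 of 5 lower (median -2.53) and basophil genes 4 of 5 lower (median -2.36). In the order given, camera adjusted p = 7.1e-23, 6.9e-08, 0.0013 and 0.022, and p = 0.0094, 0.084, 0.084 and 0.11 with an estimated correlation. Markers of lymphoid, erythroid and of hepatic, stromal and endothelial cells had a median of at most 0.172 CPM (library size alone) at wild-type day 5, with Il7r the most abundant of them. Lists also up were G2/M with 13 of 14 higher (median 1.27), G1/S with 15 of 16 higher (median 0.77), cholesterol synthesis with 19 of 20 higher (median 0.93) and glycolysis and hypoxia with 14 of 17 higher (median 1.05). The camera adjusted p = 2.3e-07, 3.9e-07, 3.1e-07 and 1.1e-06, and p = 0.063, 0.088, 0.14 and 0.14 with an estimated correlation. Primary granule genes were 8 of 9 higher (median 2.67), late neutrophil genes 10 of 18 higher (median 1.16) and ribosome biogenesis genes 13 of 17 higher (median 0.78). For these, camera adjusted p = 2.2e-06, 3.8e-04 and 1.7e-04, and p = 0.084, 0.24 and 0.072 with an estimated correlation. Adjusted over the list alone, the only other counts were late neutrophil 10 up and 1 down. In edgeR 5420 genes differed, 2708 higher and 2712 lower, 49.96% higher, 50.6% with upper-quartile factors and 59.9% with no scaling.

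**Figure D3:**
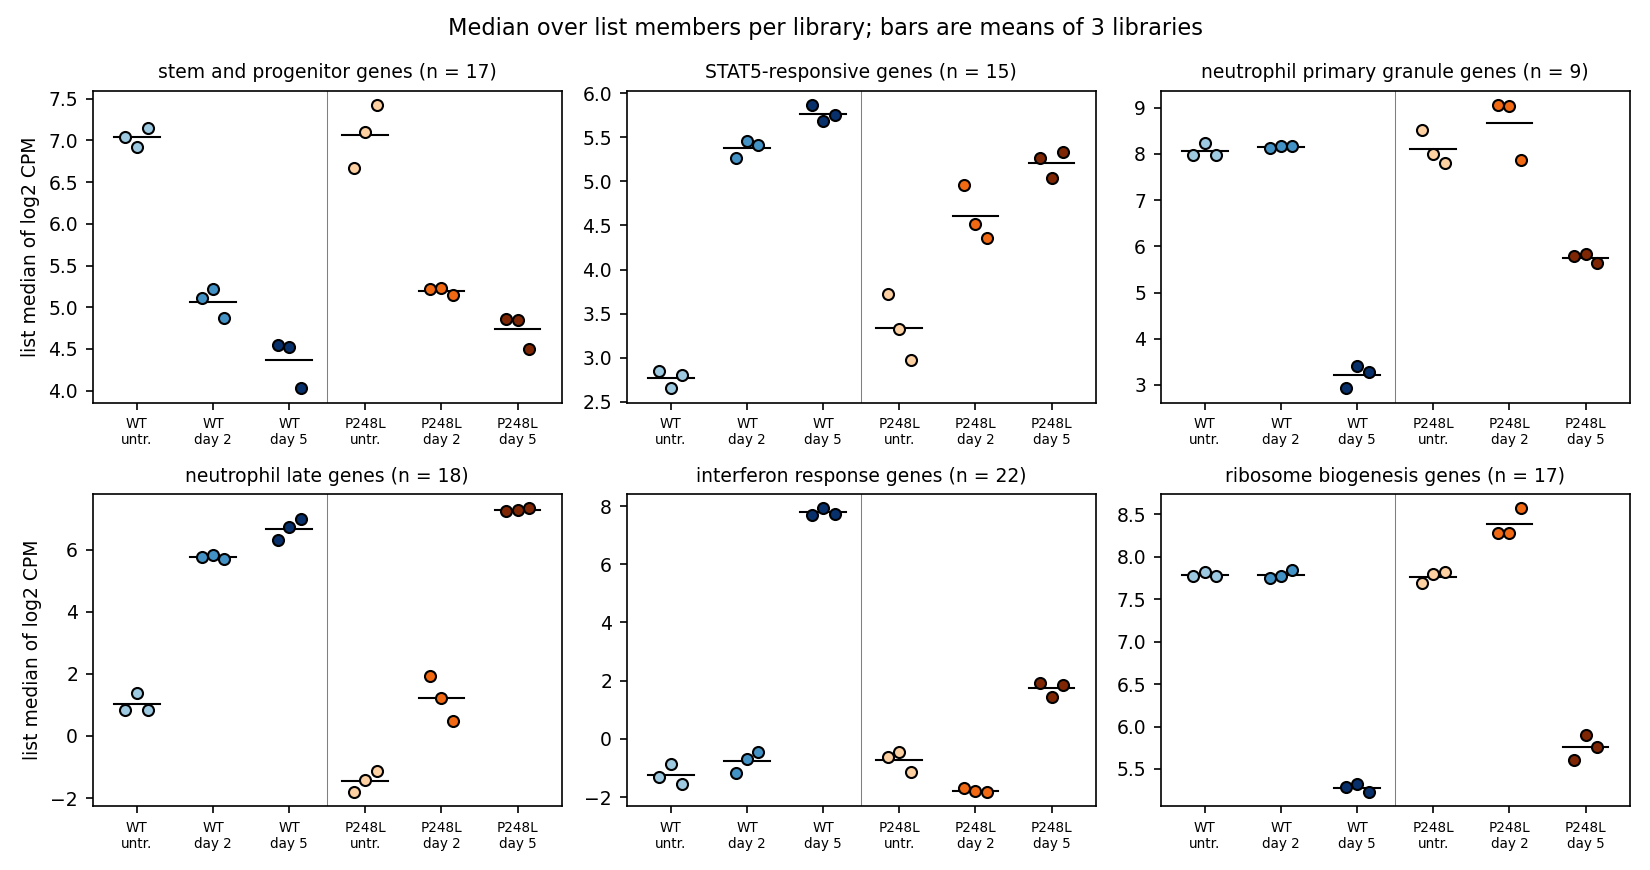
Median log2 CPM over the members of 6 gene lists in each library (points) by group, with bars at the means of 3 libraries. At day 5 every wild-type library lies at least 5.78 log2 units above every P248L library in the interferon response list.

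Whether the responses themselves differed between the lines was tested as an interaction, in which a negative difference marks a lower log2 fold change in P248L cells. At day 2 the rise of Ccl6 was smaller and the fall of Kit weaker in P248L cells. Kit fell by 4.15±0.22 in wild-type and by 1.49±0.20 in P248L cells (difference 2.65±0.28), and Ccl6 rose by 8.04±0.44 and 4.0±0.40 (difference -4.04±0.55). Egr1 differed by -3.67±0.47, the glucose transporter gene Slc2a3 by -3.79±0.38 and the cytokine gene Osm by -3.03±0.39. Cd177 went from 0.197±0.0883 to 163±32.5 CPM in wild-type cells and stood at 0.211±0.0945 and 0.522±0.0949 CPM in P248L cells (difference -8.17±0.85). The laminin gene Lama5 (-8.09±1.23), the cell cycle inhibitor gene Cdkn2b (-8.08±0.82) and the multi-copy stefins Stfa3 (-8.17±1.24) and Stfa2 (-7.63±1.33) followed (Cdkn2b had 1 read in P248L day 2 cells). Positive differences were largest for Nrg2 (4.09±0.41), S1pr3 (3.57±0.28), Elavl2 (3.56±0.56), Rassf4 (3.49±0.34) and Myl10 (3.45±0.43). Of the index genes, Csf2rb (-1.45±0.22) and Csf2rb2 (-1.61±0.19) also differed, and Il3ra did not pass (edgeR adjusted p = 0.61). The largest edgeR adjusted p among the genes that differed was 9.8e-04 (Stfa2). Responses were smaller in late neutrophil genes (1 of 18 higher and 11 lower, median -2.74), chemokine genes (8 of 13 lower, median -2.44), MAPK feedback genes (1 of 17 higher and 8 lower, median -1.27) and STAT5-responsive genes (4 of 15 lower, median -1.05). By camera, adjusted p = 1.3e-08, 5.8e-09, 6.6e-05 and 7.1e-04, and p = 0.082, 0.079, 0.084 and 0.14 with an estimated correlation. So were those of basophil genes (1 of 5 lower, median -2.07), genes shared with mast cells (4 of 5 lower, median -1.70) and eosinophil genes (1 of 6 higher and 3 lower, median -3.55). Here camera gave adjusted p = 5.2e-04, 3.7e-04 and 0.014, and p = 0.057, 0.079 and 0.19 with an estimated correlation. Cholesterol synthesis (4 of 20 lower, median -0.52), p53 and apoptosis (4 of 11 lower, median -0.95), lysosome (5 of 16 lower, median -0.27) and glycolysis genes (1 of 17 higher and 2 lower, median -0.37) also had lower responses. Their camera adjusted p = 7.2e-05, 0.0030, 0.024 and 0.036, and p = 0.24, 0.067, 0.43 and 0.51 with an estimated correlation. Higher responses were those of ribosome biogenesis (1 of 17 higher, median 0.33) and stem and progenitor genes (3 of 17 higher and 1 lower, median 0.51). List by list, camera adjusted p = 0.0013 and 0.0014, and p = 0.081 and 0.14 with an estimated correlation. With adjustment over the list alone, the only other counts were chemokine 0 up and 10 down, MAPK feedback 1 up and 10 down, STAT5-responsive 0 up and 8 down, basophil 0 up and 3 down, cholesterol synthesis 0 up and 11 down, p53 and apoptosis 0 up and 8 down and stem and progenitor 5 up and 1 down. The STAT5 median was -0.45 without P248L untreated library 1 and day 2 library 3, and with the length and GC trend removed the glycolysis list no longer passed (camera adjusted p = 0.095). Without these 2 libraries the glycolysis and lysosome lists were lost (camera adjusted p = 0.10 and 0.077, medians -0.18 and -0.14), as without each of 4 and 3 single libraries (up to 0.11 and 0.062). With the replicate block in P248L untreated and day 2 the eosinophil list did not pass (0.067). In edgeR 1126 responses differed, 357 higher and 769 lower in P248L cells. The count was 1868 without P248L untreated library 3, 1905 without P248L day 2 library 1, 2643 with the length and GC trend removed and 2980 with the block.

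At day 5 the responses of interferon response genes were lower in P248L cells. Ifit2, an interferon-induced antiviral protein, stood at 12±0.446 and 616±78.8 CPM in wild-type cells and at 15.7±4.6 and 7.36±0.839 CPM in P248L cells (difference -6.76±0.34). Mpo fell by 10.12±0.36 and 4.72±0.28 (difference 5.40±0.37), and S100a8 went from 31.7±8.2 to 4374±1383 CPM in wild-type and from 1.2±0.724 to 14043±3340.2 CPM in P248L cells (difference 6.33±0.51). Cpa3 differed by -5.90±0.29 and the asparagine synthetase gene Asns by 2.74±0.16. Rragd (-14.34±1.58), Plekhg1 (-10.23±0.78) and the interferon-induced Rtp4 (-9.14±0.31), Ifit3 (-7.85±1.16) and Mx2 (-7.48±0.88) had the most negative differences. The most positive were Serpinb9e (13.87±3.01) and the chitinase-like gene Chi3l3 (9.36±0.89), both of multi-copy families and so uncertain, Hpgd (9.09±2.10), Elane (8.0±0.66) and Nrg2 (7.29±1.42). Serpinb9e, Chi3l3, Hpgd, Nrg2, Rragd and Plekhg1 had 3 reads or fewer in a group, so their fitted differences depend on the prior count. Kit did not pass (edgeR adjusted p = 0.62) and Il3ra differed by -1.32±0.48. Among the genes that differed the largest edgeR adjusted p was 0.0495 (Il3ra). Lower responses were found in interferon response (19 of 22 lower, median -5.21), lysosome (13 of 16 lower, median -1.28), STAT5-responsive (1 of 15 higher and 6 lower, median -0.67), histone (3 of 14 lower, median -0.96), genes shared by mast cells and basophils (3 of 5 lower, median -2.40), basophil (1 of 5 lower, median -0.80) and oxidative phosphorylation genes (3 of 16 lower, median -0.55). Camera gave adjusted p = 1.4e-24, 1.5e-08, 0.023, 0.010, 0.0011, 0.047 and 0.036 in this order, and p = 0.0094, 0.079, 0.32, 0.23, 0.084, 0.16 and 0.51 with an estimated correlation. Higher responses were found in primary granule (8 of 9 higher, median 3.17), late neutrophil (12 of 18 higher, median 2.41), G2/M (12 of 14 higher, median 1.34), G1/S (11 of 16 higher, median 0.74), cholesterol synthesis (13 of 20 higher, median 0.78), glycolysis (9 of 17 higher, median 0.84) and ribosome biogenesis genes (6 of 17 higher, median 0.35). In the order given, camera adjusted p = 2.5e-08, 8.8e-08, 7.0e-08, 2.9e-05, 1.8e-05, 1.2e-04 and 0.023, and p = 0.075, 0.088, 0.057, 0.14, 0.22, 0.24 and 0.17 with an estimated correlation. By adjustment over the list alone, the only other counts were lysosome 0 up and 14 down, STAT5-responsive 1 up and 7 down, genes shared by mast cells and basophils 0 up and 4 down, oxidative phosphorylation 0 up and 5 down, G1/S 12 up and 0 down, cholesterol synthesis 15 up and 0 down and glycolysis and hypoxia 11 up and 0 down. With the length and GC trend removed the STAT5, ribosome biogenesis, histone, oxidative phosphorylation and basophil lists no longer passed (camera adjusted p = 0.073, 0.071, 0.086, 0.14 and 0.15), and with DESeq2 size factors the basophil list did not pass (camera adjusted p = 0.054). Without P248L untreated library 1 and day 2 library 3 the STAT5, basophil and oxidative phosphorylation lists were lost (camera adjusted p = 0.15, 0.094 and 0.094, the last with a median of -0.18). Without 1 library they were lost for P248L untreated library 1 (0.11), for 10 libraries (up to 0.088) and for 6 (up to 0.13). In edgeR 3188 responses differed, 1744 higher and 1444 lower, 54.7% higher and 72.6% with no scaling.

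Across the 11942 tested genes, which are not independent replicates, log2 fold changes of the lines correlated at Pearson's r = 0.64 at day 2 (Spearman correlation 0.62) and 0.82 at day 5 (Spearman correlation 0.83). The responses share no library, and the jackknife SE over libraries was 0.072 and 0.020. The total least squares slope of P248L on wild-type was 0.65 at day 2 and 0.86 at day 5. At day 2, 1349 genes rose in both lines where 485 would by independent lists, 1550 fell in both (555) and 132 moved in opposite directions. At day 5, 3312 rose in both (1483), 3456 fell in both (1613) and 229 moved apart. Mast cell, erythroid, and hepatic, stromal and endothelial lists had 2, 3 and 4 tested members and no list test, and mitochondrially encoded mRNAs had no entry in the files. Of these members, Cma1, Mitf, Gata1, Beta-s, Epor, Afp, Pdgfra and Kdr rose and Pdgfrb fell at wild-type day 5. The megakaryocyte list passed in no contrast, the smallest camera adjusted p being 0.055 for P248L against wild-type at day 2 (1 of 9 higher and 6 lower), p = 0.14 with an estimated correlation. There it passed with the replicate block (0.035), with DESeq2 size factors (0.041) and without each of 6 single libraries (0.033 to 0.047).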

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

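Tests chosen only after the result was seen were the count of separated STAT5-responsive genes, the gap between libraries for the interferon list and the day 5 value for a delay. The first of these replaced a test of whether the STAT5-responsive median in P248L cells at day 2 lay above 1, which its value of 1.07 passed only narrowly. The differences of responses below are past the threshold of the interaction test in edgeR, or in camera for lists, and are listed because the lines differed. With an estimated correlation no list passed at day 2 and only the interferon list at day 5 (camera adjusted p = 0.0094).

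At day 2, 1126 responses differed. List medians of the difference were -1.05 (STAT5-responsive), -1.27 (MAPK feedback), 0.51 (stem and progenitor), -2.74 (late neutrophil), -2.07 (basophil), -1.70 (shared mast cell and basophil), -3.55 (eosinophil, from low counts), 0.33 (ribosome biogenesis), -0.52 (cholesterol synthesis), -0.37 (glycolysis), -0.95 (p53), -2.44 (chemokine) and -0.27 (lysosome). Genes were Nrg2 (4.09), S1pr3 (3.57), Elavl2 (3.56), Rassf4 (3.49), Myl10 (3.45), Cd177 (-8.17), Stfa3 (-8.17), Lama5 (-8.09), Cdkn2b (-8.08) and Stfa2 (-7.63).

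At day 5, 3188 responses differed. List medians were -0.67 (STAT5-responsive), 3.17 (primary granule), 2.41 (late neutrophil), -0.80 (basophil), -2.40 (shared mast cell and basophil), 0.74 (G1/S), 1.34 (G2/M), 0.35 (ribosome biogenesis), 0.78 (cholesterol synthesis), 0.84 (glycolysis), -0.55 (oxidative phosphorylation), -5.21 (interferon), -1.28 (lysosome) and -0.96 (histone). Genes were Serpinb9e (13.87), Chi3l3 (9.36), Hpgd (9.09), Elane (8.0), Nrg2 (7.29), Rragd (-14.34), Plekhg1 (-10.23), Rtp4 (-9.14), Ifit3 (-7.85) and Mx2 (-7.48). Fitted values of genes with 3 reads or fewer in a group depend on the prior count.

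On the other strand, outside the comparisons, 146 features at wild-type day 5 and 172 at P248L day 5 had counts above those of the gene strand and higher than in untreated cells, of 4587 tested.

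Interferon response genes were lower in P248L than in wild-type cells at day 5 (list median -5.31). Scaling was argued against by a median nearest to 0 under 3 other scalings of -5.20, and a few odd libraries by the lowest wild-type library lying 5.78 log2 units above the highest P248L library. RNA of lymphoid, erythroid, hepatic, stromal or endothelial cells was argued against by list medians of at most 0.172 CPM (by library size alone) at wild-type day 5, where their most abundant genes were Il7r (209.8 CPM), Beta-s (7.3 CPM) and Pdgfra (14.8 CPM). The receptor may be the source, but with 1 line per receptor it cannot be separated from the line.

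Late neutrophil genes were lower in P248L than in wild-type cells at day 2 (list median -4.99; camera adjusted p = 7.5e-14, lost at p = 0.056 with an estimated correlation). P248L libraries without exposure to IL-3 were argued against by 11 of 15 STAT5-responsive genes with every day 2 library above every untreated one, where chance gives 5%. Shared reads between gene copies were argued against by a median of -4.99 in the 14 members outside multi-copy families, and a transcript length trend by a median of 0.0391 over 1000 draws of length-matched genes. Before IL-3 the list median was already -2.35 (camera adjusted p = 3.1e-04, lost at p = 0.23 with an estimated correlation), which a slower course alone would not give. For the remainder a slower course in P248L cells stays open as a hypothesis: at day 5 the list median against wild-type was 1.16. Line and receptor may each set that course, which was not tested.

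In P248L cells 12 genes had 3 reads or fewer over 9 libraries and at least 5 CPM in each wild-type library (0 genes the other way; at 1 CPM and no reads, 27 and 0): Fam135a (chromosome 1, 24010758 to 24100484), Rnf217 (10, 31501887 to 31609725), Chchd10 (10, 75933130 to 75937750), Gphn (12, 78217325 to 78684772), Cpped1 (16, 11803684 to 11909476), Fpgt (3, 155084915 to 155093387), Mtus2 (5, 147957275 to 148316065), Tmem159 (7, 120102342 to 120120987), Zc3h12c (9, 52109569 to 52168730), Lonrf3 (X, 36328358 to 36366857), Arhgap12 and C330018D20Rik. The 5 CPM rule itself set expected P248L reads high (at least 926 per gene), so depth was not tested. Reads on the other strand were argued against by a highest share of 0.0971%. Deleted segments spanning an expressed neighbour were found for 0 of 12 genes, although the neighbour of Fpgt, Tnni3k, also had few reads (4, against 2.53 CPM in wild-type cells). Smaller deletions and silencing may each be the source, and neither was tested.

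Other splits of the libraries were counted for each comparison. Splits of 3 against 3 libraries number 10, too few for a share under 0.05, and in each of the 9 comparisons 1 split, the real one, gave as many genes. The highest other split gave 2757 genes against 4762 for P248L day 2 against untreated (it parted 1 same-number pair, and the 3 others that parted 3 pairs, as the real one did, gave 0) and 0 in the other 8 comparisons (real counts 5223, 8723, 8429, 8474, 8372, 2571, 4253 and 5420). For differences of responses, 4 of 100 splits gave as many as the real 1126 at day 2. At day 5, 1 of 100 gave as many as the real 3188. These shares decide nothing, since 90 splits mixed the lines of that day (at most 723 and 342 genes). The 9 others that parted them gave 798 to 2388 and 2038 to 3133.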

How the results depend on the processing

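Tests chosen only after the data were seen, such as 2 doubted libraries left out, are listed with the processing. At an adjusted p under 0.05 with at least 2-fold change, the counts were 2378, 5692 and 5315 for wild-type day 2, day 5 and day 5 against day 2, 1746, 5343 and 5401 for P248L, 1116, 1877 and 2558 for P248L against wild-type untreated, at day 2 and at day 5, and 1859 for the day 5 response, smaller by construction. With adjusted p under 0.01, 3165 genes changed in P248L at day 2, 1339 differed untreated, and 576 and 1902 responses differed at day 2 and day 5. With fits of only the libraries compared the counts were 1630 for P248L day 2, 1177 untreated and 718 for the day 2 response, from fewer samples. With the length and GC trend removed 2643 day 2 responses differed (the cause was not tested).

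Leaving out 1 library in turn gave 4419 to 6013 genes for wild-type day 2, 8237 to 9282 for day 5, 7869 to 8987 for day 5 against day 2, 3988 to 5494, 7876 to 8917 and 7833 to 8850 for P248L, 1517 to 4541, 3351 to 5064 and 4574 to 6223 between lines, and 784 to 1905 and 2480 to 4011 for the differences of responses. The report names libraries behind the untreated and day 2 response counts. The correlation of the lines' responses ranged from 0.571 to 0.647 at day 2 and 0.802 to 0.820 at day 5.

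Without P248L untreated library 1 (low Mki67, median deviations of 0.62 in the shortest and -0.54 in the longest 20% of genes, the widest of any library, though 2 others had larger Spearman correlations with length, -0.71 and 0.69 against -0.66) and P248L day 2 library 3 (high Rn45s), 1343 day 2 and 4071 day 5 responses differed, and 2353 genes differed untreated.

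Of the 128 list results past the threshold, 10 stayed so with an estimated correlation, the cause being the correlation itself: ribosome biogenesis in 5 contrasts, interferon response in 4 and monocyte and macrophage genes in 1. With 1 library left out 124 to 133 list results passed, and without the 2 doubted libraries 9 were lost and 7 gained. Lists that passed only in some settings, besides those in the report, were eosinophil at wild-type day 2 (lowest camera adjusted p = 0.041), G2/M (0.025) and glycolysis (0.011) at P248L day 2, and p53 (0.022) at P248L day 5 against day 2. Between lines they were cholesterol synthesis (0.0095) untreated, eosinophil (0.012), oxidative phosphorylation (0.019) and histone (0.047) at day 2, macrophage (0.043) at day 5, and G1/S (0.049), oxidative phosphorylation (0.032) and interferon (0.032) in the day 2 response. With fry, 204 list results passed by direction and 254 in either direction. Histone genes at wild-type day 5 reversed with directional fry (adjusted p = 0.00377, not past the threshold in camera; the cause was not tested). No median of these lists changed sign under DESeq2, upper-quartile or no scaling.

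Of up to 980 named gene results, 1 was weaker and 10 stronger with DESeq2, 1 and 3 with limma-voom, 4 and 1 with DESeq2 factors, 2 and 0 with upper-quartile factors, 6 and 0 with no filter, 1 and 1 with the CPM filter, 2 and 4 with the replicate block, 32 and 5 with only the libraries compared, 16 and 5 with no scaling, 4 and 1 with both strands, 1 and 1 without Rn45s, 9 and 17 with the trend removed and 18 and 8 without the 2 doubted libraries. The median log2 fold change of all genes moved by more than 0.1 with no scaling, from 0.00 to -0.17 at wild-type day 2, -0.05 to -0.49 at day 5 and 0.02 to -0.25 between them, -0.01 to -0.12 and -0.02 to -0.25 at P248L day 2 and day 5, 0.02 to 0.14 between lines at day 5 and 0.04 to 0.25 in the day 5 response. Upper-quartile factors moved it at P248L day 2 (to -0.11), and DESeq2 factors at wild-type day 5 (to 0.07) and day 5 against day 2 (to 0.12). The majority of calls also turned with DESeq2 factors at wild-type day 5, P248L day 2, P248L day 5 (52% up) and in the day 5 response (49.7% higher), with upper-quartile factors at wild-type day 2 and between lines at day 5, and with no scaling at P248L day 5 against day 2 (48.2% up).

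Over all same-number pairs the correlations had a median of 0.05 against -0.01 for others. With the number as a block in all libraries, 4900 genes changed at P248L day 2, 2512 differed untreated and 1177 responses differed at day 2. As a block in P248L untreated and day 2 alone it gave 6184 and 2980 and ended the list calls given in the report, brought in the G2/M list at P248L day 2 and 6 named gene results, and changed no other call. Depth limits genes with few counts, which the filter did not all remove: Il5ra, for example, had 1 to 6 reads in each day 5 library.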

Other observations

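Genes in this part were chosen after their values were seen. Ifnb1, which encodes interferon beta, had 20 reads over the wild-type day 5 libraries (5 to 10 in each) and 0 in the other 15 libraries. Ifna2 and Ifna4 had 2 reads each and Ifnab 1 read at wild-type day 5, and 0 elsewhere. Ifnk had 4 reads at wild-type day 5, 1 at P248L day 2, 3 at P248L day 5 and 0 elsewhere. Csf1, the macrophage growth factor, stood at 4.7±0.343, 23.5±7.32 and 754±26.7 CPM in wild-type untreated, day 2 and day 5 cells, and at 7.2±0.756, 7.45±0.935 and 338±73.8 CPM in P248L cells. Slc40a1, the iron exporter ferroportin, stood at 97.7±8.9 against 1.56±0.137 CPM at day 5, and Fth1, ferritin heavy chain, at 22090.1±1548 against 5738±594 CPM.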
